A study of mouse gut metagenome with 48 samples.

How the data were processed

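Stool from 12 male C57BL/6 mice, aged 8 to 10 weeks and bearing GL261 glioma cells in the brain, was sampled at 4 time points, which gave 48 libraries in 8 groups of 6. Per the labels' protocols, DNA was extracted from stool, a V3 to V4 fragment of 16S rDNA was amplified with the 341F and 805R primers, a synthetic plasmid was spiked in as an internal reference, and paired reads were sequenced on an Illumina instrument. Trim Galore 0.4.5 is named in the submitters' processing notes. The tool that clustered operational taxonomic units (OTUs), the taxonomy database and its confidence threshold are not given in the sources used here, so genus names are those the authors assigned.

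Values of 2 kinds were deposited. The first is a table of read counts of 973 OTUs, deposited by the authors after each library had been drawn down to 133560 reads. The second is a score, the absolute number of 16S copies of each of 981 OTUs, which the authors set from the spike-in plasmid and rounded to whole numbers; the amount of stool or DNA it refers to is not given in the sources used here, so it is used to compare libraries and not as copies per gram. Among the counts 16 OTUs, and among the absolute values 14, were at 0 in all 48 libraries. OTU numbers differ between the tables, so both were summed to the genus, or to the lowest named rank where no genus was given ("unclassified" bins): 126 bins in the count table, 104 of them named genera, and 127 in the absolute table. The unclassified bins held 56.3% of reads.

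The absolute values were not proportional to the reads. Within each library the copies followed a power of the reads, with an exponent between 1.03 and 1.12 (median 1.09) and 26.8 to 215 copies at 1 read. Inverting that curve gave whole numbers of reads, within 0.1, for 100% of the values up to 1000 reads in each library, and so the depth before subsampling: 153965 to 279937 reads, median 207874. These recovered reads, and copies taken as proportional to them, served as alternatives chosen after the data were seen. Equal depth makes the count table comparable between libraries: 3 reads, the floor used for a group with no reads, are 0.00225% of a library. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

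Genera were tested on read counts with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, TMM normalization, at least 10 counts in at least 6 of the libraries fitted). Comparisons within mice and the differences of changes came from 1 fit of the 48 libraries with the mouse as a block, and comparisons between arms at 1 time from the 12 libraries of that time. Absolute copies were tested on log2(value + 27) with limma 3.58.1 (trend, mouse block where the count fit had it). The pseudocount is about the copies worth of 1 read in the library where that was lowest. Fold changes of rare genera on that scale depend on it. They could lie below the count values (Turicibacter in TMZ mice at T3 against T1, 7.69 against 10.2). Others lay above them (Bifidobacterium between the arms at T2, 7.86 against 6.16). A genus was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Total 16S load (log2 of summed copies), Shannon diversity (natural log) and summed taxon lists (log2 of percent + 0.01) were tested 2-sided with exact permutation tests: sign flips of the change per mouse within mice, and all 924 assignments of the 12 mice between arms. With 6 mice the smallest p such a paired test can give is 0.03125, and between arms 0.00216. Load and diversity were adjusted over 11 comparisons each. Communities were compared with PERMANOVA on Bray-Curtis distances between OTU counts with the same exact permutations; F values equalled those of vegan 2.7.1 at all 4 time points. The differences of changes have no PERMANOVA.

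The labels give each mouse a number, and libraries with the same number come from the same animal, which is where the pairing comes from. As a check, deviations from the group means on the log scale correlated at 0.134 on average between libraries of the same mouse, with a range of -0.433 to 0.656, and the averages of vehicle mice 19 (-0.00479) and 14 (0.0307) were near 0, so the pairing rests on the labels. Libraries of the same group differed far beyond sampling noise (chi-square per degree of freedom at least 133), so none was counted as a duplicate. The labels used here name no cage, litter or sequencing batch.

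The taxa the text names were chosen by a rule: per comparison, up to 10 higher and 10 lower genera by smallest adjusted p, or the 3 with the smallest p where none passed; per taxon list, up to 4 of its most abundant members; and the 5 most abundant genera. The taxon lists were short-chain fatty acid producers, lactic acid bacteria with bifidobacteria, mucin degraders, Bacteroidales genera, Erysipelotrichales genera, gut Proteobacteria, segmented filamentous bacteria, contamination markers, diet or host organelle DNA, each phylum, and the ratio of Firmicutes to Bacteroidetes. The design, the lists, the naming rule and the alternatives listed at the end were fixed before the data were examined. The segmented filamentous bacteria list had 0 members among the bins and was not tested, which left 20 lists over 11 comparisons, adjusted together over 220 tests.

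These alternatives were total counts without TMM, DESeq2 1.42.0 with poscounts size factors, no low-count filter, a filter of 50 counts, a pseudocount 10 times larger, no low-value filter, no mouse block, other scales and diversity indices, other distances (Jaccard, Aitchison on counts + 0.5, Bray-Curtis at genus level), lists in absolute copies or with a pseudocount of 0.1 percent, and leaving out each mouse in turn. The genus tests were tested on simulated counts, in 10 runs per comparison. Counts were drawn from a negative binomial with 1 mean per genus over all libraries, the dispersion of each genus and a random mouse effect. Each run changed many genera at once, about as many up as down, and more than edgeR called in any real comparison. Arm differences before gavage were not simulated. The rates below hold for that setting only and are not recovery rates of the real tests. For the arms at T2, 26.2% of genera changed 4-fold, 84.8% changed 16-fold and 100% changed 64-fold were recovered from counts, 0 in the wrong direction, and 1.72% of unchanged genera were called. For the change from T1 to T2 in the TMZ arm, the shares recovered were 32.4%, 87.1% and 98.5%, for T0 to T1 in both arms 63.6%, 97.1% and 98.4%, and for the difference of T1-to-T2 changes 13.2%, 72.9% and 86.8%. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.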

Results

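The gut bacteria of glioma-bearing mice were followed by 16S rDNA sequencing of stool from 12 animals. GL261 cells, a mouse glioma line that grows in C57BL/6 mice, were implanted into the brain of all 12. Temozolomide (TMZ), an oral alkylating drug used against glioma, was given by gavage to 6 mice at 50 mg/kg per day on days 8 to 12. The other mice received the vehicle, 0.5% sodium carboxymethyl cellulose. Stool was collected on day 1 with the implantation (T0), on day 7 before any gavage (T1), on day 14 (T2) and on day 28 (T3), so each arm had 6 libraries per time point. Every library held 133560 reads after subsampling by the authors, spread over 448 to 613 OTUs (median 541). The 5 most abundant bins were unclassified_Porphyromonadaceae, a Bacteroidales family (32.9% of all reads), unclassified_Lachnospiraceae, a family rich in fermenting Clostridia (14.4%), Bacteroides (7.35%), the mucin degrader Akkermansia (4.42%) and Barnesiella (3.88%).

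The first comparison asked how the microbiota moved from implantation to day 7, before either gavage. Lactobacillus and Barnesiella fell, and Odoribacter and Intestinimonas rose. Lactobacillus, a lactic acid producer, fell from 2.28% ± 1.4 to 0.402% ± 0.638 of reads (SD, n = 12; log2 fold change -3.07 ± 0.66 SE, adjusted p = 0.00296) and was lower in 11 of 12 mice. Odoribacter, a butyrate-producing genus of the Bacteroidales, rose from 0.629% ± 0.72 to 2.91% ± 1.94 (2.49 ± 0.58, adjusted p = 0.00423; 11 of 12 mice). Barnesiella, also of the Bacteroidales, fell from 5.45% ± 2.45 to 2.34% ± 0.809 (-1.34 ± 0.34, adjusted p = 0.00803; 11 of 12 mice). Intestinimonas, which makes butyrate from sugars and lysine, rose from 0.165% ± 0.0633 to 0.591% ± 0.63 (1.57 ± 0.45, adjusted p = 0.0147; 10 of 12 mice). On absolute copies its adjusted p was 0.0895. Coprobacter, which makes propionate and acetate, fell from 3.97% ± 2.38 to 2.06% ± 1.07 (adjusted p = 0.0209; 9 of 12 mice). Rarer genera that fell were Anaerofustis (-2.94 ± 0.78, adjusted p = 0.0109; 10 of 12 mice), unclassified_Clostridiaceae_1 (-3.45 ± 0.99, 0.0147; 8 of 12) and unclassified_Coriobacteriaceae, from 0.122% to 0.0699% (0.0286; 10 of 12). Of 67 genera, 2 rose and 6 fell; DESeq2 called 5 higher and 9 lower. The count was 5 without TMZ mouse 2 or vehicle mouse 12, and without 1 mouse the calls ended of Intestinimonas (TMZ 11, vehicle 12 or 15; adjusted p up to 0.127), unclassified_Clostridiaceae_1 (TMZ 01, 2 or 9; up to 0.082), Coprobacter (TMZ 2, vehicle 12 or 34; up to 0.0955) and unclassified_Coriobacteriaceae (TMZ 2 or 9, vehicle 12, 15 or 19; up to 0.101). Without the mouse block the calls of unclassified_Clostridiaceae_1 (0.16) and unclassified_Coriobacteriaceae (0.0768) ended, and without the count filter those of Coprobacter (0.0842) and unclassified_Coriobacteriaceae (0.113).

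The vehicle arm shows the course of the microbiota without the drug, in which time, glioma growth and, after T1, gavage of the vehicle cannot be separated, since all 6 mice had all of them. By day 14 Escherichia/Shigella had risen and unclassified_Erysipelotrichaceae had fallen. Escherichia/Shigella, facultative anaerobes of the Enterobacteriaceae, rose from 0.0392% ± 0.00711 at T0 to 2.26% ± 1.91 at T2 (SD, n = 6; log2 fold change 5.78 ± 1.13 SE, adjusted p = 0.000794; 5 of 6 mice). Its share at T3 was 0.0353% ± 0.0119. Unclassified_Erysipelotrichaceae, a Firmicutes family, fell from 2.2% ± 1.79 to 0.176% ± 0.0563 (-3.56 ± 0.94, adjusted p = 0.0136; 6 of 6 mice). Intestinimonas rose from 0.148% ± 0.0326 to 0.689% ± 0.396 at T2 (2.25 ± 0.63, adjusted p = 0.0187; 6 of 6 mice), with an adjusted p of 0.052 on absolute copies. At T3 it was at 1.4% ± 0.929 (3.16 ± 0.65, adjusted p = 0.00184; 6 of 6 mice), and 1 genus of 67 passed. Clostridium_XlVa, a cluster with many butyrate producers, rose from 0.177% ± 0.16 to 0.615% ± 0.263 at T2 (1.81 ± 0.57, adjusted p = 0.0259; 5 of 6 mice). The lactic acid bacterium Lactococcus went from 1 read over the 6 libraries at T0 to 296 at T2, a ratio of 296 (95% exact interval 52.7 to 11730 for counting error; adjusted p = 0.00933; higher in 4 and lower in 1 of 6 mice). Mouse 12 held 236 of these reads, and without it the ratio was 60 (10.4 to 2409). Parasutterella (-2.22 ± 0.66, adjusted p = 0.0231), Mobilitalea (-6.59 ± 1.98, 0.0231; lower in 4 of 6 mice), Aestuariispira (-3.06 ± 0.95, 0.0259) and unclassified_Bacteroidetes (-1.95 ± 0.63, 0.0288) also fell by T2. On absolute copies Mobilitalea (adjusted p = 0.119) and unclassified_Bacteroidetes (0.0951) did not pass. In total 4 genera rose and 5 fell at T2, where DESeq2 called 7 higher and 9 lower; at T3 DESeq2 called 2 higher and 2 lower.

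Some vehicle calls were lost when a mouse was left out. Escherichia/Shigella and unclassified_Erysipelotrichaceae passed at T2 without each of the 6 mice. Intestinimonas and Clostridium_XlVa passed at T2 only without mouse 17 (adjusted p without another mouse up to 0.091 and 0.182), with log2 fold changes of 1.92 to 2.14 and 1.38 to 1.68 in the 5 fits where they did not pass. Calls ended of Lactococcus without mouse 12 (log2 fold change 5.21, 0.0589), Parasutterella without 12 or 34 (up to 0.103), Mobilitalea without 14 or 34 (up to 0.197, with -4.45 without 34), Aestuariispira without 15, 17, 19 or 34 (up to 0.182, with -2.31 without 34; -4.29 without 12, where it passed) and unclassified_Bacteroidetes without 12, 15, 17 or 34 (up to 0.182). Larger log2 fold changes were seen for Lactococcus without mouse 14 (8.32) and for Mobilitalea without 17 (-7.71) or 19 (-7.87), and these calls held. The count at T2 was 5 without mouse 12 or 15 and 3 without 34. At T3 the call of Intestinimonas ended without mouse 14 (0.0774), which left 0 genera with edgeR and 7 at an unadjusted p under 0.05, and 2 genera passed without mouse 12, 17 or 19. Without the mouse block Parasutterella, Mobilitalea and Aestuariispira had an adjusted p of 0.0632 at T2.

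In the TMZ arm Bifidobacterium rose after gavage. Bifidobacterium, a fermenter of oligosaccharides, went from 0.00574% ± 0.0109 at T1 to 0.118% ± 0.0887 at T2 (SD, n = 6; log2 fold change 6.75 ± 1.55 SE, adjusted p = 0.00764; 6 of 6 mice), and 1 genus of 67 passed, against 5 higher and 0 lower with DESeq2. On absolute copies its change was 6.74 (adjusted p = 0.0045). At T3 it stood at 0.235% ± 0.332 (5.72 ± 1.57, adjusted p = 0.0288; higher in 4 and lower in 1 of 6 mice; 0.0534 on absolute copies). Turicibacter, a genus of the Erysipelotrichales, had no reads in the TMZ libraries of T1 and 0.163% ± 0.309 at T3, at least 72.5-fold higher against a floor of 3 reads per library (adjusted p = 0.0122; 6 of 6 mice). Mouse 7 held 1057 of its 1305 reads at T3, and without it the bound was 16.5-fold (adjusted p = 0.0467). Its share at T3 in the vehicle arm was 0.206% ± 0.433. At T3, 2 genera of 67 passed. The Bifidobacterium call at T2 ended without TMZ mouse 11 (0.103), with 0 genera called by edgeR and 11 at an unadjusted p under 0.05, and without the mouse block (4.38, adjusted p = 0.147), with 0 and 8. At T3 it ended without TMZ mouse 01, 11 or 2 (up to 0.155, with 4.31 without 01), which left 1 genus without 01 or 2, and without the block (0.0538), and 4 genera passed without TMM, which moved the median of all genera by 0.50.

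**Figure D1:**
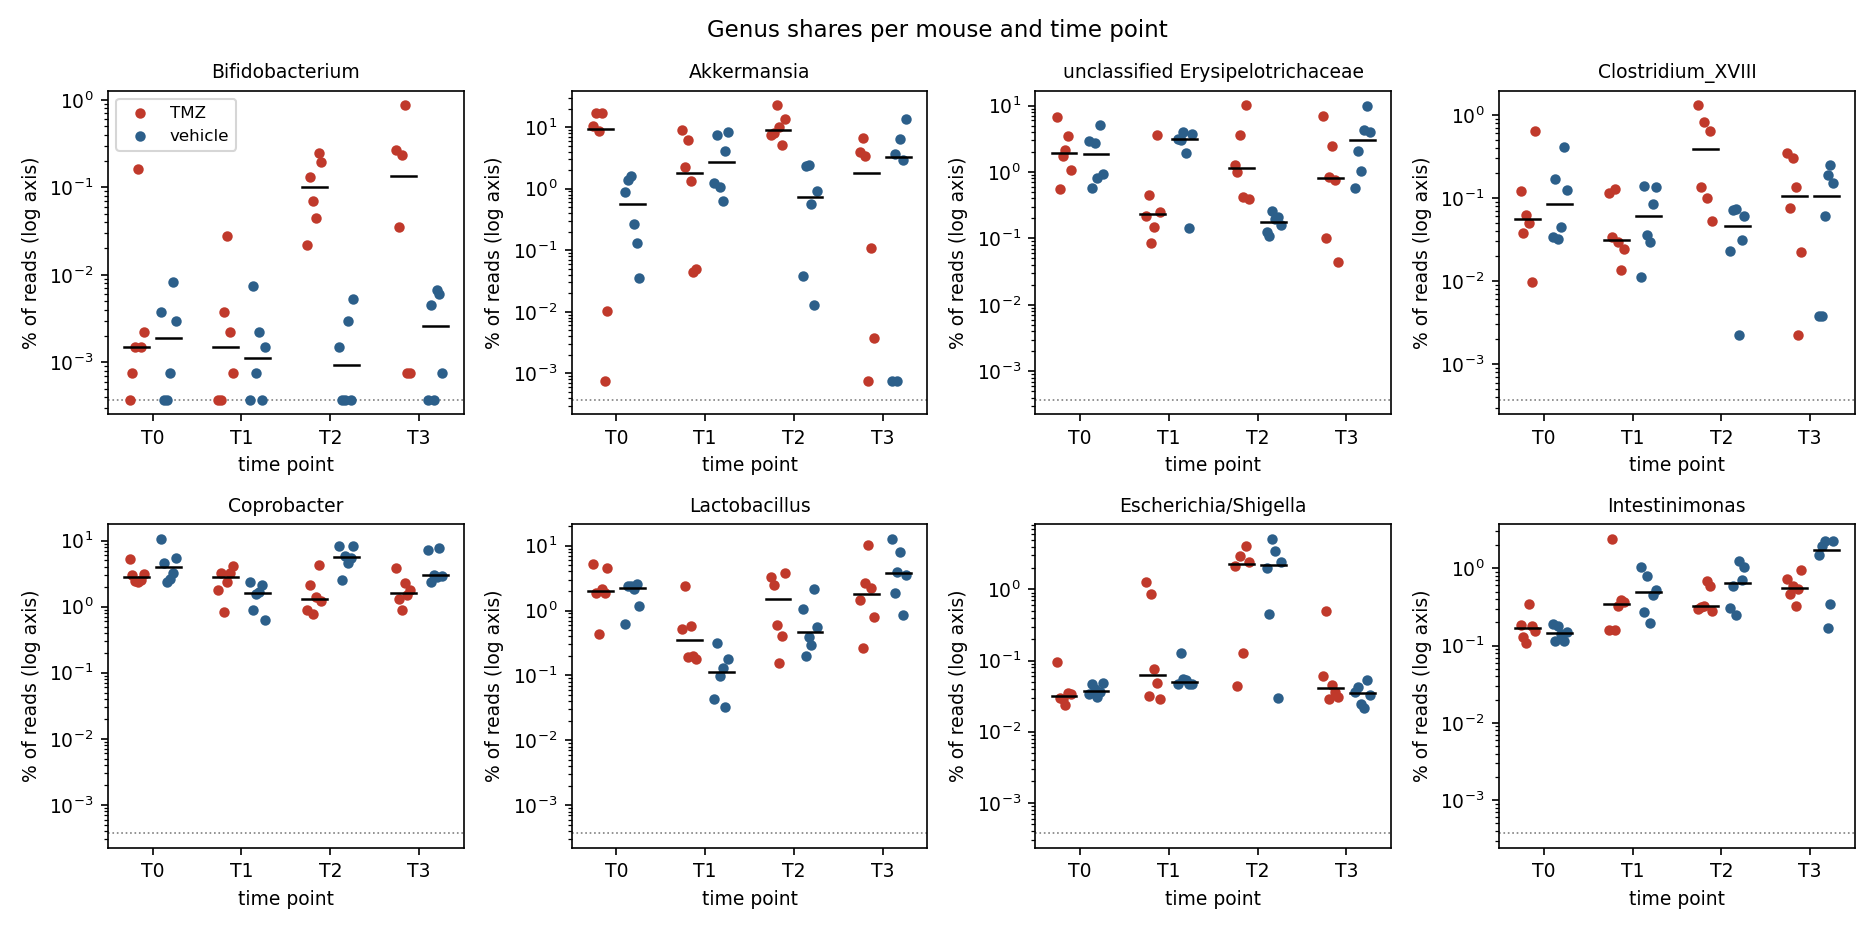
Percent of reads (log axis) of 8 genera in each mouse at T0, T1, T2 and T3, with colours for the arms; black lines are group medians and libraries with no reads lie on the dotted line at 0.5 reads. At T2 all 6 TMZ mice lie above every vehicle mouse for Bifidobacterium, Akkermansia and unclassified Erysipelotrichaceae.

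Before gavage the arms were compared to see how alike they started. No genus passed at T0 or T1. Akkermansia at T0 was at 8.73% ± 7.51 in the TMZ arm and 0.71% ± 0.665 in the vehicle arm (SD, n = 6 each; log2 difference 3.55 ± 1.49 SE, adjusted p = 0.621), with 4 TMZ mice above every vehicle mouse. Coprobacillus (2.46 ± 0.93; 0.93 without TMZ mouse 9) and Acetatifactor (-1.89 ± 0.87; -0.49 without vehicle mouse 17) had the same adjusted p. At T1 Akkermansia was at 3.14% ± 3.65 in the TMZ arm and 3.75% ± 3.34 in the vehicle arm. The smallest p values at T1 belonged to Aestuariispira (-2.66 ± 0.71, adjusted p = 0.102), the butyrate producer Roseburia (4.45 ± 1.27, 0.102) and Lactobacillus (2.63 ± 0.82, 0.107), which was at 0.67% ± 0.843 in the TMZ arm and 0.133% ± 0.105 in the vehicle arm. At T0 edgeR called 0 of 53 genera (4 at an unadjusted p under 0.05), limma on absolute copies 0 and DESeq2 0. At T1 edgeR called 0 of 56 (7 unadjusted), limma 0 and DESeq2 5, 3 of them higher and among them Aestuariispira (0.00216) and Lactobacillus (0.0174). At T1, 6 genera passed without TMZ mouse 8, with Aestuariispira, Roseburia and Lactobacillus at an adjusted p of 0.0475, and 2 without TMZ mouse 11 (Roseburia 0.0403). Without TMZ mouse 7 the difference of Roseburia was 1.47 (adjusted p = 0.422).

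On day 14, after the 5 days of gavage, 5 genera were higher in TMZ-treated than in vehicle-treated mice and 0 were lower. Akkermansia, which feeds on intestinal mucin, made up 11.2% ± 6.3 of reads in the TMZ arm and 1.05% ± 1.09 in the vehicle arm (SD, n = 6 each; log2 difference 3.38 ± 0.95 SE, adjusted p = 0.0325). Bifidobacterium was at 0.118% ± 0.0887 against 0.00162% ± 0.00214 (6.16 ± 1.09, adjusted p = 0.00136) and unclassified_Erysipelotrichaceae at 2.8% ± 3.78 against 0.176% ± 0.0563 (4.19 ± 0.88, adjusted p = 0.00452). For these genera all 6 TMZ mice lay above every vehicle mouse. Clostridium_XVIII, a genus of the Erysipelotrichales, was at 0.505% ± 0.5 against 0.0438% ± 0.0292 (3.60 ± 0.96, adjusted p = 0.0275; 5 TMZ mice above every vehicle mouse). Coprobacillus was at 0.235% ± 0.513 against 0.00936% ± 0.012 (4.92 ± 1.43, adjusted p = 0.0332; 2 mice above). On absolute copies Akkermansia differed by 5.76 (adjusted p = 0.00293), while Coprobacillus did not pass (4.62, adjusted p = 0.0789) and differed by 4.15 already at T1. Escherichia/Shigella was at 1.95% ± 1.59 in the TMZ arm and 2.26% ± 1.91 in the vehicle arm (-0.14, adjusted p = 0.921). The phylum Bacteroidetes held 41.9% ± 8.65 of reads in the TMZ arm and 61% ± 13 in the vehicle arm (-0.54, exact p = 0.0216, adjusted p = 0.286), but differed by 0.01 in absolute copies. Of 55 genera 5 passed with edgeR, against 9 with DESeq2 (6 higher, 3 lower), 6 without TMM (5 higher, 1 lower) and 2 with the filter of 50 counts, where Akkermansia had an adjusted p of 0.0544.

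Leaving out single mice changed most of these calls at T2. Unclassified_Erysipelotrichaceae passed without each of the 12 mice (lowest log2 difference 3.10, without TMZ 8). Bifidobacterium passed without each of the 6 vehicle mice, and without any TMZ mouse it had too few libraries above the count filter to be tested. Akkermansia ended without TMZ 2, 7 or 9 or vehicle 17 or 34 (adjusted p up to 0.156), with a log2 difference of 2.76 without TMZ 2, 3.13 without TMZ 9 and 3.43, 3.54 and 3.57 without TMZ 7, vehicle 17 and vehicle 34. The calls also ended of Clostridium_XVIII without TMZ 2 or vehicle 12 (up to 0.119) and of Coprobacillus without TMZ 2 or vehicle 12, 15, 17 or 34 (up to 0.293). TMZ 2 held 1.28% of reads as Coprobacillus and the other TMZ mice at most 0.0344%, and without it the log2 difference was 1.46. The count was 1 without TMZ 2, 3 without TMZ 7 or 9 or vehicle 12 or 34, and 10 without TMZ 8.

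By day 28 no genus passed between the arms on counts. Vampirovibrio, a genus described from a predator of algae, was at 0.937% ± 0.555 in the TMZ arm and 0.104% ± 0.119 in the vehicle arm (SD, n = 6 each; log2 difference 2.87 ± 0.75 SE, adjusted p = 0.0512), with all 6 TMZ mice above every vehicle mouse. It was the 1 genus that passed on absolute copies (3.78, adjusted p = 0.0354). Coprobacter was at 1.93% ± 1.04 against 4.35% ± 2.42 (-1.95 ± 0.51) and Olsenella, a lactic acid producer, at 0.0615% ± 0.0707 against 0.6% ± 0.517 (-4.19 ± 1.15), both also at an adjusted p of 0.0512. Akkermansia was at 2.37% ± 2.8 in the TMZ arm and 4.42% ± 5.03 in the vehicle arm. edgeR called 0 of 56 genera (14 at an unadjusted p under 0.05), limma on absolute copies 1, and DESeq2 13, 4 higher and 9 lower, among them Vampirovibrio and Coprobacter (0.000733) and Olsenella (0.000605). Without vehicle mouse 15, 4 genera passed on counts, with Vampirovibrio, Coprobacter and Olsenella at 0.0408, and without TMM 1 passed, with the median of all genera moved by 0.66.

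The change over the gavage period, from T1 to T2, differed between the arms for 8 of 67 genera. Unclassified_Erysipelotrichaceae went from 0.785% ± 1.36 to 2.8% ± 3.78 with TMZ, higher in 6 of 6 mice (SD, n = 6 each). With vehicle it went from 2.66% ± 1.42 to 0.176% ± 0.0563, lower in 5 of 6. The difference of log2 changes was 6.04 ± 1.31 SE (adjusted p = 0.00368). In the TMZ mice it had held 0.564% to 6.77% at T0, which overlaps the 0.398% to 10.1% at T2. Coprobacter went from 2.58% ± 1.19 to 1.78% ± 1.31 with TMZ, lower in 5 of 6, and from 1.53% ± 0.67 to 5.78% ± 2.2 with vehicle, higher in 6 of 6 (-2.39 ± 0.60, adjusted p = 0.00904). Parabacteroides, a Bacteroidales genus, went from 1.22% ± 0.963 to 2.62% ± 1.49 with TMZ and from 2.29% ± 0.755 to 1.5% ± 0.976 with vehicle (2.28 ± 0.69, adjusted p = 0.0226). Bifidobacterium was higher in 6 of 6 TMZ mice and in 3 of 6 vehicle mice (7.11 ± 2.17, adjusted p = 0.0226). Aestuariispira (4.85 ± 1.29, adjusted p = 0.011), unclassified_Clostridiales (2.01 ± 0.60, 0.0226) and unclassified_Bacteroidetes (2.77 ± 0.92, 0.0392) also had the higher change with TMZ. Their mean T1 levels in the TMZ and vehicle arms were 0.0362% and 0.231%, 0.502% and 1.26%, and 0.285% and 0.718%. They fell in 6, 5 and 6 of 6 vehicle mice. In TMZ mice Aestuariispira and unclassified_Clostridiales rose in 5 of 6, while unclassified_Bacteroidetes fell in 4 of 6. Lactococcus had the lower change with TMZ (-8.46 ± 2.16, adjusted p = 0.00904). It was at 0.00961% ± 0.00857 and 0.002% ± 0.00453 with TMZ (lower in 5 of 6 mice). With vehicle it was at 0.000624% ± 0.000875 and 0.0369% ± 0.0689 (higher in 4, lower in 2), where mouse 12 held 236 of the 296 reads at T2. Akkermansia had a difference of 7.43 and an adjusted p of 0.0599. In all 6 changes were higher and 2 lower with TMZ, and with DESeq2 11 were higher and 6 lower. From T1 to T3 Coprobacter was the 1 genus that passed (-2.37 ± 0.61, adjusted p = 0.0274). It was at 1.93% ± 1.04 at T3 with TMZ and 4.35% ± 2.42 with vehicle, where it was higher than at T1 in 6 of 6 mice. The vehicle changes of Coprobacter started from a T1 level below T0 in 6 of 6 mice. Against T0, vehicle T3 was higher in 3 and lower in 3 mice. In TMZ mice T1 was higher than T0 in 3 and lower in 3, and T3 was lower than T0 in 6 of 6.

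Of the 8 genera, unclassified_Erysipelotrichaceae, Coprobacter and Lactococcus passed without each of the 12 mice, with Lactococcus at -7.25 without vehicle 12, -9.92 without TMZ 01, -9.58 without TMZ 7 and -9.56 without vehicle 19. Aestuariispira ended without TMZ 7 or vehicle 14 (adjusted p up to 0.0724, with 3.69 without vehicle 14) and Bifidobacterium without TMZ 11, 2, 8 or 9 or vehicle 14, 15 or 17 (up to 0.144, with 5.42 without vehicle 14). Unclassified_Clostridiales passed only without TMZ 9 or vehicle 19 (otherwise up to 0.133), Parabacteroides only without TMZ 01 or vehicle 34 (up to 0.21) and unclassified_Bacteroidetes only without TMZ 01 or vehicle 19 (up to 0.243, with 1.64 without TMZ 8). The count was 4 without TMZ 11, 2, 7 or 8 or vehicle 14, 5 without TMZ 9 or vehicle 15 or 17, and 3 with the filter of 50 counts. Without the mouse block Bifidobacterium (0.165) and Parabacteroides (0.0911) did not pass, nor did Bifidobacterium with the filter of 50 counts (0.0608). Unclassified_Clostridiales, Parabacteroides and unclassified_Bacteroidetes did not pass on the reads before subsampling (0.0639, 0.0822 and 0.0822), without a count filter (0.082 each) or with the filter of 50 counts (0.0654 each), nor unclassified_Bacteroidetes without TMM (0.0673). On absolute copies unclassified_Clostridiales (0.082) and unclassified_Bacteroidetes (0.163) did not pass. The T3 call of Coprobacter held only without TMZ 01 or vehicle 14, 15 or 19 (otherwise up to 0.114), with 2 genera without TMZ 01 or vehicle 19. On the reads before subsampling it ended (0.055), with 0 genera called by edgeR and 10 at an unadjusted p under 0.05; 3 were higher and 1 lower without TMM, which moved the median of all genera by 0.57, and 5 higher and 3 lower with DESeq2.

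Absolute copies, which do not sum to a constant, were tested with limma. From T0 to T1, 2 of 87 genera rose and 6 fell, and 5 passed without TMZ mouse 01 or 2. In vehicle mice 3 rose and 5 fell at T2, Escherichia/Shigella among the former (5.11); 2 passed without mouse 12, 5 without 14 or 17, 1 without 15 or 34 and 3 without the mouse block. At T3 Intestinimonas passed (3.17, adjusted p = 0.00706), with 2 genera without mouse 12 or 19 and 0 without 14, 15 or 34. In TMZ mice Bifidobacterium was the 1 genus at T2, with 2 genera without mouse 01 or 7 or the block and 3 without 11. Turicibacter (adjusted p = 0.00441) and Parabacteroides (1.98, adjusted p = 0.0279), the latter named after its values were seen, passed at T3, with 1 genus without mouse 7. Between the arms 1 genus passed at T1 without TMZ mouse 7, against 0 with all mice. At T2, 4 of 71 genera were higher with TMZ: Akkermansia, Bifidobacterium (7.86), Clostridium_XVIII (4.35) and unclassified_Erysipelotrichaceae (3.92). At T3 the 1 genus, Vampirovibrio, became 0 without TMZ 11 or 2 or vehicle 12 or 34, 2 without TMZ 01, 8 or 9 or vehicle 17, 6 without vehicle 14 and 7 without TMZ 7. The T1-to-T2 changes of 4 genera were higher and of 2 lower with TMZ, with 3 genera without TMZ 8, 1 without TMZ 9 and 2 without vehicle 15 or 34. Coprobacter was the 1 genus for T1 to T3 (-2.48, adjusted p = 0.0471), with 2 without TMZ 2 and 0 without TMZ 11, 7 or 9 or vehicle 12, 14, 15, 17 or 34 or the block.

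**Figure D2:**
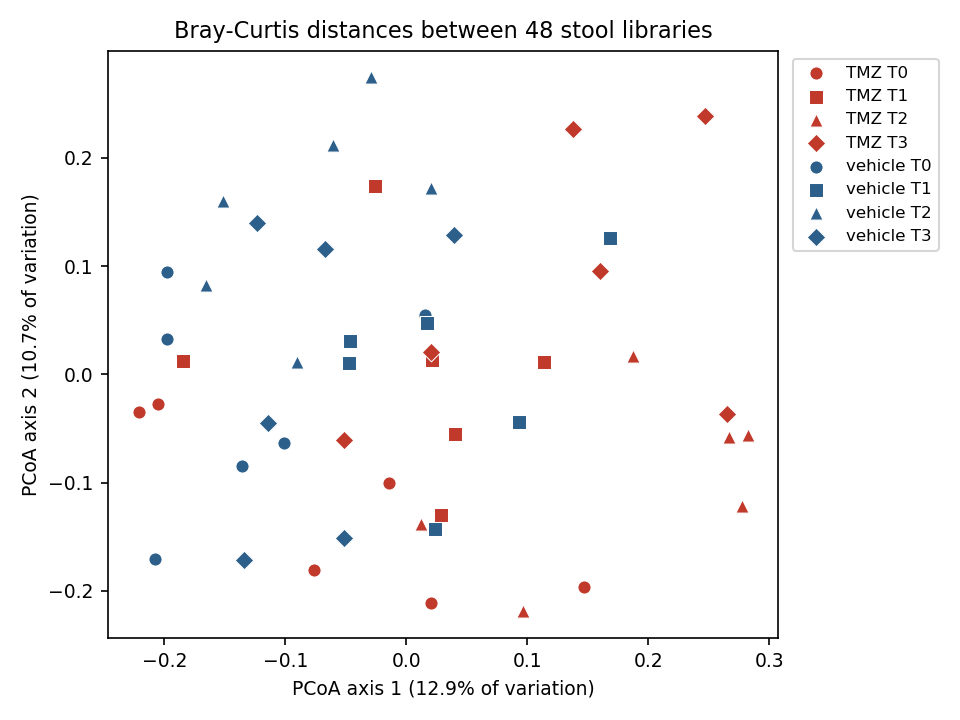
Principal coordinates of Bray-Curtis distances between the 48 libraries, 1 point per library, with colours for the arms and shapes for the time points. Axis 1 holds 12.9% and axis 2 10.7% of the variation.

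The community as a whole differed between the arms at T1, T2 and T3 and moved with time in both arms. Between arms, the share of Bray-Curtis variation explained (R2) was 11% at T0 (exact p = 0.212), 20.8% at T1 (exact p = 0.00649), 27% at T2 (exact p = 0.00216, the smallest possible) and 21.7% at T3 (exact p = 0.00649; n = 6 per arm). From T0 to T1 the shift in both arms had an R2 of 10.5% (exact p = 0.000488, the smallest possible with 12 mice). Against T0 the vehicle arm had an R2 of 19.9% at T2 and 23.2% at T3, and against T1 the TMZ arm had 17.6% at T2 and 16.8% at T3, each at the smallest exact p of 6 pairs (0.03125). Adjusted over these 9 comparisons the p was at most 0.0352 except at T0. With genera in place of OTUs the R2 and exact p were 10.3% and 0.312 at T1, 17% and 0.0974 at T3, 22.1% and 0.188 for vehicle T2, 20.4% and 0.0625 for vehicle T3 and 14.5% and 0.156 for TMZ T3, so these calls ended. After adjustment the genus-level differences of the arms at T2 (24%, exact p = 0.026) and of TMZ T2 (16.05%, 0.03125) did not pass either (0.0938 for both). The T0 difference reached 15.5% without TMZ mouse 9 (exact p = 0.0455, adjusted p = 0.0584), and a comparison of 5 pairs cannot pass, since its smallest p is 0.0625.

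Total 16S load differed between the arms before any treatment. At T0 it was 35.9 ± 9.04 M copies (M, mega) in the TMZ arm and 23 ± 3.91 M in the vehicle arm (SD, n = 6 each; log2 difference 0.62, exact p = 0.00433, adjusted p = 0.0476). The difference was 0.35 at T1 (exact p = 0.13), 0.60 at T2 (exact p = 0.0887) and -0.14 at T3 (exact p = 0.359). The exact tests called 0 of the other 10 comparisons of load. Shannon diversity passed in 0 of 11 comparisons, 2 of which had an unadjusted exact p under 0.05. It was 0.23 higher at T1 than at T0 (exact p = 0.00977, adjusted p = 0.107; n = 12 mice). At T3 it was 4.52 ± 0.2 in the TMZ arm and 4.13 ± 0.312 in the vehicle arm (exact p = 0.0346, adjusted p = 0.185). The load call at T0 held only without TMZ mouse 8 or vehicle mouse 19 (adjusted p up to 0.119 without another mouse), and with copies proportional to reads the difference was 0.78 (exact p = 0.0108, adjusted p = 0.119). The diversity difference between T1 and T0 passed without vehicle mouse 14 or 17 (adjusted p = 0.043, exact test).

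**Figure D3:**
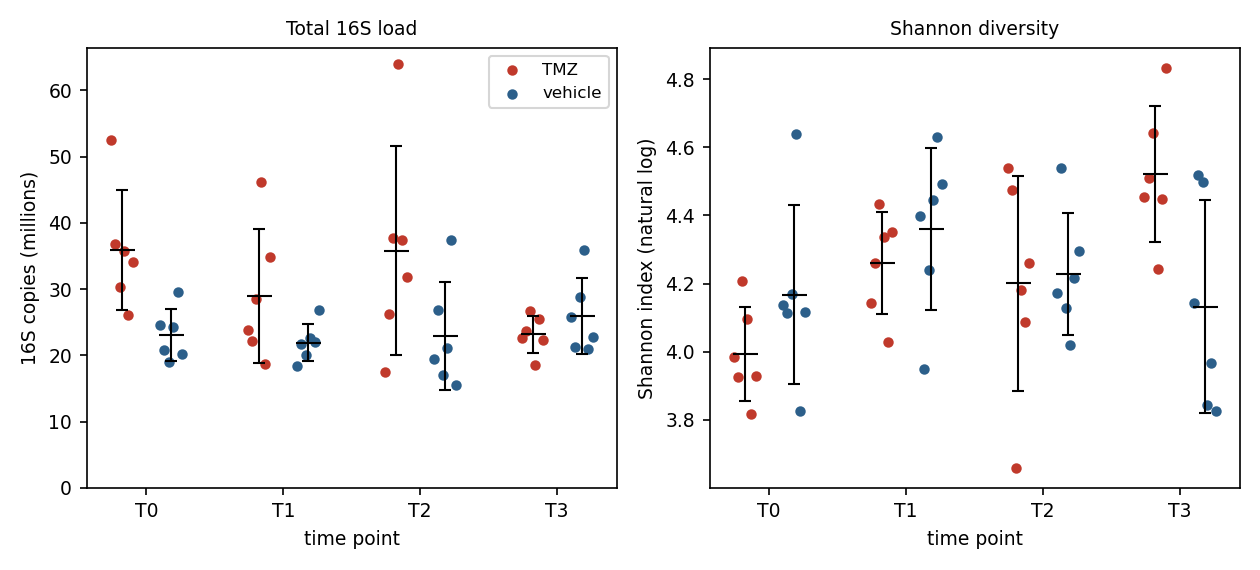
Total 16S load in M (mega) copies and Shannon diversity with the natural log by time point, with colours for the arms; points are mice, and bars are the mean and 1 SD of 6 mice. At T0 the mean load was 35.9 M in the TMZ arm and 23 M in the vehicle arm.

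Among the taxon lists fixed in advance, 0 of 220 exact tests passed after adjustment (smallest adjusted p 0.0952), and 29 had an unadjusted p under 0.05. Short-chain fatty acid producers made up 3.15% ± 1 of reads in TMZ and 3.61% ± 1.47 in vehicle mice at T0, and 6.83% ± 2.38 and 10.5% ± 2.17 at T1 (SD, n = 6 each; log2 change 1.37, exact p = 0.000488, adjusted p = 0.0952). Of 9 members tested, Odoribacter and Intestinimonas rose and 0 fell, over all genera and adjusted over the list alone; Oscillibacter, Eubacterium and Clostridium_IV did not pass. Lactic acid bacteria with bifidobacteria had a change of -2.95 over the same week (exact p = 0.000977, adjusted p = 0.0952), and 1 of 4 members, Lactobacillus, fell over all genera and adjusted over the list alone; Streptococcus did not pass. Mucin degraders were at 3.89 more with TMZ than with vehicle at T2 (exact p = 0.00216, adjusted p = 0.0952). Of the 2 members Akkermansia passed over all genera and adjusted over the list alone, and Mucispirillum, which lives in the mucus layer, did not (1.32, adjusted p = 0.482). Erysipelotrichales genera had a difference of T1-to-T2 changes of 3.06 (exact p = 0.00216, adjusted p = 0.0952), with 0 of the 2 members passing over all genera by edgeR and 2, Clostridium_XVIII and Turicibacter, adjusted over the list alone. In TMZ mice this list was at 0.0574% ± 0.0507 at T1 and 0.506% ± 0.499 at T2 (n = 6). The log2 change was 2.49 (exact p = 0.03125, the smallest possible, adjusted p = 0.286). The list does not hold unclassified_Erysipelotrichaceae, which was at 0.785% ± 1.36 and 2.8% ± 3.78 in these groups, so it is not the share of the order.

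Bacteroidales genera had a difference of -0.42 between TMZ and vehicle at T2 in percent (exact p = 0.0368, adjusted p = 0.295) and of 0.15 in absolute copies. None of the 6 members passed there over all genera or adjusted over the list alone. Unclassified_Porphyromonadaceae was at 23.2% ± 5.7 with TMZ and 32.9% ± 6.06 with vehicle, Bacteroides at 4.89% ± 3.62 and 7.88% ± 2.91, Barnesiella at 2.62% ± 1.46 and 4.48% ± 3.56, and Alistipes at 2.74% ± 1.48 and 3.58% ± 1.4 (SD, n = 6 each). Gut Proteobacteria had their smallest p between the arms at T0 (0.74, exact p = 0.0758). Of their 3 members tested in vehicle mice at T2, Escherichia/Shigella rose and Parasutterella fell over all genera and adjusted over the list alone, and Bilophila, which respires taurine sulfite, did not pass. Contamination markers, which include Staphylococcus, Ralstonia, Acinetobacter and Corynebacterium, had their smallest p in TMZ mice between T1 and T2 (-1.47, exact p = 0.0625). There 0 of 2 members tested passed over all genera by edgeR, and Staphylococcus passed adjusted over the list alone (log2 fold change -4.68, adjusted p = 0.187 over all genera), though its reads were lower in 2 and higher in 1 of 6 mice. The list was at 0.181% ± 0.351 at T1 and 0.0122% ± 0.00732 at T2 (SD, n = 6). Organelle DNA was represented by Streptophyta at no more than 5 reads in a library (smallest exact p = 0.0606).

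Of the phyla, Verrucomicrobia had a difference of 4.68 between the arms at T2 (exact p = 0.00216, adjusted p = 0.0952). Its levels at T2 equalled those of Akkermansia, which also makes up most of the mucin degraders, so these are not separate results. Tenericutes had a difference of T1-to-T2 changes of 3.33 (exact p = 0.00866, adjusted p = 0.212). Deferribacteres differed by 3.91 between the arms at T3 (exact p = 0.026). Firmicutes changed by 0.39 from T0 to T1 (exact p = 0.0376), and their ratio to Bacteroidetes by 0.61 (exact p = 0.043). Proteobacteria (0.84) and Candidatus_Saccharibacteria (0.75) had their smallest exact p, 0.03125, in vehicle mice at T2 against T0, and Actinobacteria the same p in vehicle mice at T3 against T0 (1.31) and in TMZ mice at T2 against T1 (1.21). For Cyanobacteria/Chloroplast the smallest exact p was 0.0606, between the arms at T2. For Nitrospirae and Parcubacteria, each seen in 1 group, it was 1.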

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

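The tests of the genera higher with TMZ at T2, of the shape of the spike-in curve and of other splits of the mice were chosen after the results were seen, and those of single mice, of low-count OTUs and of dominant OTUs before.

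The first pattern is the set of 5 genera higher with TMZ than with vehicle at T2. These 5 were picked for their arm difference at T2, and a change to T2 uses the same values, which lowers its exact p. The differences at T1 do not use those values. On reads they were -1.52 for Akkermansia, 0.50 for Bifidobacterium, -0.33 for Clostridium_XVIII and -2.52 for unclassified_Erysipelotrichaceae. At T2 they were 4.87, 6.30, 3.25 and 3.06, so a T1 difference of that size is argued against. The highest exact p of the change from T1 to T2, on reads and absolute copies, was 0.00433 for unclassified_Erysipelotrichaceae and 0.00649 for the others. Coprobacillus (0.981) differed by 4.15 in absolute copies at T1 (exact p = 0.0455), so a T1 difference stays open for it. At T0 the arms differed on reads by 0.84 for Bifidobacterium and 0.26 for unclassified_Erysipelotrichaceae, so a T0 difference of the T2 size is argued against for both. Their highest exact p of the change from T0 to T2 was 0.013 and 0.0238. A T0 difference stays open for Coprobacillus (0.372) and Clostridium_XVIII (0.0519). The mean log2 difference of Clostridium_XVIII on reads was -0.36 at T0, -0.33 at T1 and 3.25 at T2. A T0 difference also stays open for Akkermansia (0.262), at 1.16, -1.52 and 4.87, while the count model gave 3.55 at T0 and 3.38 at T2. In absolute copies the median log2 difference of the 5 at T2 was 4.62. They were picked for their shares, and copies follow the same reads. The total load was not lower with TMZ at T2 (0.60, exact p = 0.0887), so a low median was out of reach. That median therefore does not decide whether a fall of other taxa raised the shares. All 5 of 5 genera passed on the reads before subsampling. The counts were drawn from those reads, so this shows only that the draw did not make the calls. In TMZ mice unclassified_Erysipelotrichaceae held 0.564% to 6.77% of reads at T0 and 0.398% to 10.1% at T2, so the ranges overlapped. In vehicle mice it held 0.107% to 0.259% at T2 and 0.567% to 9.76% at T3, so its T2 difference goes with a low vehicle level. For Bifidobacterium and unclassified_Erysipelotrichaceae an effect of TMZ stays open as a hypothesis. Differences between cages, which the labels do not name and which were not tested, stay open too.

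The second pattern is the difference between the communities of the arms at T1, before any gavage. A single mouse apart from the rest is argued against by the exact p without each mouse, at most 0.0173. The 357 OTUs with at least 1000 reads gave an R2 of 21% and an exact p of 0.00649, against 20.8% with all OTUs. The difference was thus seen in these OTUs. Bray-Curtis distances weigh OTUs by their reads, so leaving out rare ones could change little. The comparison therefore does not decide on low-count OTUs. At genus level the difference was not seen (R2 10.3%, exact p = 0.312). Housing by arm was not tested, since the labels name no cage, and no biological explanation was tested, since no mouse had been gavaged by T1.

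The third pattern is the higher 16S load of the TMZ arm at T0. With copies proportional to reads the log2 difference was 0.78 (exact p = 0.0108). Those copies take their value at 1 read from the fitted curve, so they cannot decide whether the curve is the source. Without the largest OTU of each library the log2 difference was 0.56 (exact p = 0.0108). That OTU held 13.7% ± 4.01 of reads in the TMZ arm and 10.3% ± 3.95 in the vehicle arm (SD, n = 6 each). Leaving it out could move the difference only a little, so this does not decide on a few dominant OTUs. With proportional copies the adjusted p over the 11 comparisons was 0.119, so the call itself did not hold. The amount of stool or DNA behind each library could not be tested, as it is not given in the sources used here. No biological explanation was tested, since no mouse had been gavaged at T0.

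The counts of genera were set against other splits of the same mice or time points. Values on counts come first and those on absolute copies second, and splits as large include the real one. In some comparisons no other split tried gave as many genera. The arms at T2 had 5 (1 of 100 splits as large, highest other 3) and 4 (1 of 100, highest other 3). T1 against T0 had 8 (1 of 100, highest other 3) and 8 (1 of 100, highest other 7). Vehicle T2 against T0 had 9 (1 of 32, highest other 4) and 8 (1 of 32, highest other 5). The difference of T1-to-T2 changes had 8 (1 of 100, highest other 5) and 6 (1 of 100, highest other 3). The 100 splits were drawn from 462 possible ones between the arms and 2048 for T1 against T0. For vehicle T2, 1 of 32 is the smallest share possible. The shares were not adjusted over the comparisons, so they argue against chance there but do not exclude it. In other comparisons further splits were as large, so chance stays open. Vehicle T3 had 1 (5 of 32 splits as large, highest other 2) and 1 (3 of 32, highest other 1). TMZ T2 had 1 (6 of 32, highest other 2) and 1 (7 of 32, highest other 2). TMZ T3 had 2 (5 of 32, highest other 3) and 2 (3 of 32, highest other 4). The difference of T1-to-T3 changes had 1 (5 of 100, highest other 5) and 1 (16 of 100, highest other 10). The arms at T3 had 1 on absolute copies (8 of 100, highest other 7). With a real count of 0 all 100 of 100 splits are as large by construction, so nothing follows between the arms at T0 (highest other 2 on counts and 1 on absolute copies), at T1 (3 and 3) or at T3 on counts (7).

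The changes that differed between the arms from T1 to T2 were those of unclassified_Erysipelotrichaceae (6.04), Aestuariispira (4.85), unclassified_Clostridiales (2.01), Parabacteroides (2.28), Bifidobacterium (7.11), unclassified_Bacteroidetes (2.77), Coprobacter (-2.39) and Lactococcus (-8.46), and from T1 to T3 that of Coprobacter (-2.37).

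In 24 of 249 groups of 6 libraries 1 mouse lay far from the others. A rate of 1 in 20 would give about 12.45, but only for independent groups of normally distributed values. Some groups had no or almost no reads in most mice, and lists hold genera that were also counted alone. No excess over chance follows from these numbers. The gap is the distance to the nearest mouse as a share of the group's log2 range, held against the critical value of Dixon's test at 1 in 20. The shares of single libraries below have 95% Wilson intervals, which cover counting error only.

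In the TMZ arm, mouse 2 stood apart at T2 for Coprobacillus (gap 0.783; 1.28% of reads, interval 1.22 to 1.34, the others at most 0.0344%). Mouse 7 stood apart for Bifidobacterium at T0 (gap 0.929; 0.162%, 0.142 to 0.185) and T1 (gap 0.760; 0.0277%, 0.0201 to 0.0382), for Turicibacter at T0 (gap 1; 0.0666%, 0.0542 to 0.082, no reads in the others), for unclassified_Clostridiaceae_1 at T2 (gap 0.795; 0.113%, 0.0964 to 0.133) and, on the low side, for mucin degraders at T3 (gap 0.692). Mouse 01 was high at T0 for Coprobacter (gap 0.651; 5.2%, 5.08 to 5.32) and Escherichia/Shigella (gap 0.763; 0.0958%, 0.0806 to 0.114) and at T2 for Lactococcus (gap 0.904; 0.0112%, 0.00681 to 0.0185). Mouse 11 was high for Intestinimonas at T1 (gap 0.680; 2.41%, 2.33 to 2.5, the others at most 0.386%) and Escherichia/Shigella at T3 (gap 0.765; 0.501%, 0.464 to 0.54), and low for Parasutterella at T0 (gap 0.663; 0.245%, 0.22 to 0.273). Mouse 9 was low for short-chain fatty acid producers at T0 (gap 0.684) and mouse 8 for mucin degraders at T1 (gap 0.633).

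In the vehicle arm, mouse 19 was low at T1 for unclassified_Erysipelotrichaceae (gap 0.782; 0.142%, 0.123 to 0.164, the others at least 1.95%), unclassified_Coriobacteriaceae (gap 0.739; 0.0127%, 0.00795 to 0.0204) and Bacteroidales genera (gap 0.737). It was high for contamination markers at T0 (gap 0.727) and at T2 for Mobilitalea (gap 0.904; 0.0112%, 0.00681 to 0.0185) and Turicibacter (gap 1; 0.0127%, 0.00795 to 0.0204, no reads in the others). Its T1 library had a mean Bray-Curtis distance of 0.573 to the other vehicle libraries of T1, and those libraries had between 0.376 and 0.416. Mouse 14 was high at T1 for Escherichia/Shigella (gap 0.834; 0.127%, 0.11 to 0.148) and gut Proteobacteria (gap 0.691), mouse 12 at T2 for Lactococcus (gap 0.667; 0.177%, 0.156 to 0.201), and mouse 17 was low at T0 for Bacteroidales genera (gap 0.713).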

How the results depend on the processing

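The reads before subsampling and the copies proportional to reads were chosen as alternatives after the data were seen. The cause of each change below was not tested, except that fewer mice raise the smallest p of exact tests. Of the results of named genera with 1 mouse left out, 101 lost and 7 gained a call.

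Counts of genera on reads moved by more than 1.5 times with DESeq2 to 14 (T1 against T0), 16 (vehicle T2), 4 (vehicle T3), 5 (TMZ T2), 5 (arms at T1), 9 (T2), 13 (T3), 17 (T1-to-T2 changes) and 8 (T1-to-T3 changes). The median of all genera moved with it by -0.13 for TMZ T2, 0.18 and -0.11 at T0 and T1, and -0.17 and -0.11 for the differences of changes. The filter of 50 counts gave 2 for vehicle T3, 2 at T2, 3 for the T1-to-T2 and 2 for the T1-to-T3 changes. No low-count filter gave 3 for TMZ T2 (1 higher, 2 lower) and 4 for TMZ T3 (2 higher, 2 lower), where the main calls were all higher. Without TMM there were 4 for TMZ T3, 1 at T3 and 4 for the T1-to-T3 changes, and the median at T1 moved by -0.32. No mouse block gave 0 with edgeR for TMZ T2 (8 at an unadjusted p under 0.05), and the reads before subsampling 0 for the T1-to-T3 changes (10 unadjusted).

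Counts on absolute copies moved without the block to 3 (vehicle T2), 2 (TMZ T2) and 0 (T1-to-T3 changes; limma, 10 unadjusted). No low-value filter gave 10 (TMZ T2), 14 (TMZ T3) and 0 (T1-to-T3 changes; 24 unadjusted). A pseudocount 10 times larger gave 4 (TMZ T3) and 2 (arms at T3). Copies proportional to reads gave 2 (TMZ T2), 1 (TMZ T3) and 0 (T1-to-T3 changes; 13 unadjusted), and a load difference at T0 of 0.78, which no longer passed.

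Diversity differences that changed sign were -0.657 by the inverse Simpson index and -9.83 by observed OTUs for vehicle T2, 0.00149 in absolute copies and 0.416 by inverse Simpson for vehicle T3, and 0.00748 in absolute copies between the arms at T2. At genus level the R2 no longer had an exact p under 0.05 before adjustment at 22.1% (vehicle T2), 20.4% (vehicle T3), 14.5% (TMZ T3), 10.3% (arms at T1) and 17% (T3). Jaccard and Aitchison distances changed 0 of the 9 calls each. In absolute copies the arm difference at T2 changed sign for Bacteroidetes (0.0115) and Bacteroidales genera (0.15).

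With 1 mouse left out, counts on reads ranged from 5 to 11 (T1 against T0), 3 to 8 (vehicle T2), 0 to 2 (vehicle T3), 0 to 1 (TMZ T2), 1 to 3 (TMZ T3), 0 to 6 (arms at T1), 1 to 10 (T2), 0 to 4 (T3), 4 to 10 (T1-to-T2 changes) and 0 to 2 (T1-to-T3 changes). On absolute copies they ranged from 5 to 10 (T1 against T0), 1 to 7 (vehicle T2), 0 to 2 (vehicle T3), 1 to 3 (TMZ T2), 1 to 3 (TMZ T3), 0 to 1 (arms at T1), 0 to 7 (T3), 1 to 8 (T1-to-T2 changes) and 0 to 2 (T1-to-T3 changes). Load ranged from -0.145 to 0.00549 for vehicle T2, the latter without mouse 34, and from 0.51 to 0.71 at T0. Diversity ranged from 0.18 to 0.27 (T1 against T0), -0.0127 to 0.197 (vehicle T2, below 0 without mouse 14 or 19), -0.12 to 0.12 (vehicle T3, above 0 without 17 or 34), -0.15 to 0.084 (TMZ T2, above 0 without 2), -0.0952 to 0.0805 (arms at T2, above 0 without TMZ 2 or vehicle 14) and -0.0183 to 0.217 (T1-to-T2 changes, below 0 without TMZ 01). R2 ranged from 19.4% to 24.6% (vehicle T2), 22.4% to 27.3% (vehicle T3), 16.6% to 20.2% (TMZ T2), 17.2% to 20.9% (TMZ T3) and 9.37% to 15.5% (arms at T0).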

Other observations

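These values were picked after they were seen, and no test was planned for them. Escherichia/Shigella was high at T2 in both arms. In the TMZ arm it was at 0.387% ± 0.545 at T1, 1.95% ± 1.59 at T2 and 0.117% ± 0.188 at T3 (SD, n = 6), higher at T2 than at T1 in 6 of 6 mice and lower at T3 than at T2 in 5 of 6. In the vehicle arm it was at 0.0626% ± 0.0319, 2.26% ± 1.91 and 0.0353% ± 0.0119, higher at T2 in 5 of 6 mice and lower at T3 in 5 of 6. The change from T1 to T2 in the TMZ arm had an adjusted p of 0.121 by edgeR. Turicibacter was higher at T3 than at T2 in 6 of 6 TMZ mice and 5 of 6 vehicle mice, and the arms at T3 had a log2 difference of -1.13 (adjusted p = 0.747).

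Akkermansia was higher at T2 than at T1 in 5 of 6 TMZ mice and lower in 5 of 6 vehicle mice. From T2 to T3 it was lower in 6 of 6 TMZ mice and higher in 4 of 6 vehicle mice. Coprobacter was lower at T1 than at T0 in 6 of 6 vehicle mice and in 3 of 6 TMZ mice. Staphylococcus in the vehicle arm was higher at T1 than at T0 in 5 of 6 mice and lower at T2 than at T1 in 6 of 6.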
